A study of Homo sapiens with 2 samples.

How the data were processed

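Total RNA of 1 untreated U2OS culture and 1 culture given 30 µM AMTB for 24 h was extracted with Trizol and made into sequencing libraries with an Illumina TruSeq RNA kit, per the labels' protocols. Libraries were assigned to groups by the treatment label. The control was labelled untreated, and no solvent control was stated. The authors deposited FPKM values (fragments per kilobase of transcript and per 1000000 fragments), rounded to 2 decimals, for 16146 Entrez Gene identifiers in both libraries, per the file headers. The genome build was GRCh38 per the submitters' processing notes. The aligner, the counting program, the annotation, any filter and the strandedness are not given in the sources used here. FPKM divides by transcript length and library total, so a gene's value also depends on what the other genes take up, and reads of near-identical paralogs can be split or lost in ways that cannot be traced from the values. Gene symbols and coordinates came from the NCBI RefSeq gene table of the same build (GRCh38), which matched 16118 of the identifiers. Of the listed genes, 15937 were protein-coding and 181 non-coding or pseudogenes. Genes of the mitochondrial chromosome were not analysed here, so the list of mitochondrially encoded genes has no value.

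FPKM are not counts, and no count model was applied. The sums of FPKM were 440138 and 432006, and 936 and 893 genes were listed at 0 in the untreated and the AMTB library. Depth was estimated from the low values. For genes with a single transcript length, FPKM under 2 and up to 6 reads, the depth was sought at which value times length gave whole reads. The best fit was 9660000 reads (untreated) and 9820000 (AMTB). At these depths 68.9% of 700 genes and 70.5% of 760 genes lay within 0.15 of a whole number, against 30% by chance. Reads behind each gene were then computed from FPKM, depth and the median length of its RefSeq-linked transcripts in GENCODE release 29. Lengths were found for 99.1% of the tested genes. The other genes were given the median length of all genes in simulations and length-based steps. Among the named genes this was TGFB3 alone, for which no interval is reported. The median was 68 reads for genes with a mean FPKM of 1 to 5, 267 for 5 to 20, 820 for 20 to 100 and 3119 above that. From these reads, 95% intervals of each FPKM ratio were computed with the exact Clopper-Pearson method. They are approximate, cover counting error only and do not cover variation between cultures.

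The measure for each gene was log2(FPKM + 1) in the AMTB library minus log2(FPKM + 1) in the untreated library. A fold on this scale understates the difference of low genes; ratios in the text are plain FPKM ratios unless a log2 value is given. Genes with a mean FPKM of at least 1 were tested against a size threshold of 2-fold. With 1 library per group there is no test, and the counts describe these libraries, not the conditions. Gene lists (39) were fixed before the data were examined. For the 34 lists with at least 5 measured genes, the median difference was ranked among 10000 random lists of the same size, matched on mean expression in 20 bins. A list was said to stand apart below the 2nd or above the 98th percentile; 10 lists did so as higher and 7 as lower. With so many lists and 4% of random lists outside these bounds, a call close to them is weak. Random lists draw genes independently, whereas the members of a list can vary together between cultures. The percentile is therefore not an error rate, even for a median beyond all 10000 random lists. The lists overlap in part: SREBF1 is in the fatty acid and the LXR list, CCN2 in the TGFβ/SMAD and the YAP/TEAD list, and GDF15 in the p53 and the ATF4 list.

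Genes are named by a rule fixed before the data were examined. It takes the 12 highest and 12 lowest differences among genes with at least 5 FPKM in 1 or both libraries, up to 4 members with the largest differences in each list described, and 12 genes named in every case, which are TRPM8 and genes of the TGFβ pathway. TM7SF2, SREBF2, EPCAM, NEDD9, VIM, NR1H2, ID1, ID2, ID3 and ID4 fall outside it and were named after their values were seen. A few other members are named without values, only to say what a list holds. Some genes that the rule takes are not reported here.

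Alternatives fixed in advance were pseudocounts of 0.1 and 0.5, no filter or a mean FPKM of at least 5, and thresholds of 1.5-fold and 3-fold. They also included rescaling each library to a sum of 1000000, centring on the median of all genes, upper-quartile scaling and a trimmed mean scaling (30% of log2 ratios and 5% of mean expression trimmed). Unmatched random lists were the last of them. After seeing the data, removal of trends with transcript length and GC content, random lists also matched on length, and versions of the TGFβ/SMAD and YAP/TEAD lists without shared members were added.

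The procedure was tested on simulated data before use, with 11484 genes drawn at the levels of these libraries. Of genes set 2.5-fold higher, 92% passed the 2-fold threshold, and of genes set 2.5-fold lower, 70%. No gene set at 1.5-fold passed, and 1 unchanged gene did. The depth step recovered 8960000 reads where 9000000 were simulated and 11960000 where 12000000 were, starting from 2349 and 2435 genes before the limits of the fit. It used the same transcript lengths as the simulation, so it cannot show the effect of wrong lengths. Of 100 lists without a shift, 6 were said to stand apart, and of 100 lists shifted by 0.5, all 100. The simulation held counting error only and lists of randomly drawn genes. It therefore does not cover variation between cultures or genes that vary together. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.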

Results

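Gene expression was measured by RNA sequencing in U2OS, a human cell line established from an osteosarcoma, a malignant bone tumour. One culture was left untreated and the other was exposed for 24 h to 30 µM AMTB. AMTB is a small molecule that blocks TRPM8, a cation channel opened by cold and menthol. The study asked what this antagonist does in osteosarcoma cells, with TGFβ signalling as the pathway of interest. Each condition was represented by 1 library, so no difference has a replicate check, and no test, standard error or p-value is given. The values were FPKM for 16146 genes. The step size of the low values corresponded to about 9660000 reads in the untreated library and 9820000 in the AMTB library. At least 1 FPKM was recorded for 11483 genes in the untreated library and for 11494 in the AMTB library. The median FPKM was 5.23 and 5.31, and the 10 most abundant genes held 7.04% and 7.35% of the summed FPKM.

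Among the gene lists, cholesterol synthesis genes (median 0.96 on the log2 scale) and amino acid and integrated stress response genes (0.39) were higher in the AMTB library. YAP/TEAD target genes (-0.23) and BMP/ID target genes (-0.40) were lower. Each of these medians lay beyond those of all 10000 random lists of like expression, a rank that does not cover variation between cultures. Among 11497 genes with a mean FPKM of at least 1, 26 were at least 2-fold higher in the AMTB library and 34 at least 2-fold lower, on the log2(FPKM + 1) scale. Most genes (96.7%) lay within 1.5-fold, and the correlation across genes was 0.99. Counting error alone, simulated in 1000 pairs of libraries with equal levels, gave a median of 1 gene and at most 6 genes beyond 2-fold in each direction. The number beyond 2-fold depended on the pseudocount, with 65 higher and 77 lower at a pseudocount of 0.1.

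Among genes with at least 5 FPKM in 1 or both libraries, the highest difference on the log2 scale belonged to INSIG1 (Entrez Gene 3638; GRCh38 chromosome 7, 155297878 to 155310235), an endoplasmic reticulum protein that restrains sterol synthesis. It measured 14.9 FPKM untreated and 55.3 FPKM with AMTB, a ratio of 3.70 with a 95% counting interval of 3.30 to 4.16. GDF15 (Entrez Gene 9518; chromosome 19, 18386158 to 18389176), a secreted stress cytokine, measured 5.44 and 20.2 FPKM, a ratio of 3.72 (2.80 to 4.99). HMGCS1 (Entrez Gene 3157; chromosome 5, 43287470 to 43313412), the enzyme that makes HMG-CoA, measured 16.4 and 52.8 FPKM, a ratio of 3.23 (2.93 to 3.56). The 12 highest genes also held ASNS, STARD4, DHCR7, CYP51A1, MVK, IDI1, MSMO1, SCD and GPNMB, at log2 differences from 1.38 for ASNS to 1.15 for GPNMB.

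At the other end stood HPD (Entrez Gene 3242; chromosome 12, 121839527 to 121888611), an enzyme of tyrosine breakdown, at 83.4 FPKM untreated and 14.0 FPKM with AMTB, 5.98-fold lower. CEMIP (Entrez Gene 57214; chromosome 15, 80779370 to 80951771), which takes part in hyaluronan breakdown, measured 21.1 and 4.62 FPKM, 4.57-fold lower. PLAT (Entrez Gene 5327; chromosome 8, 42174718 to 42207565), which encodes tissue plasminogen activator, measured 139 and 41.2 FPKM, 3.37-fold lower. The collagen gene COL8A1 measured 38.19 and 12.22 FPKM, 3.13-fold lower, and RCAN1, an inhibitor of calcineurin, 27.0 and 8.87 FPKM, 3.04-fold lower. The cytokine IL18 measured 45.7 and 17.9 FPKM, 2.55-fold lower. DDIT4L, GREM1, CRABP2, APOBEC3A, RIPOR3 and SUSD2 completed the 12 lowest, between -1.58 for DDIT4L and -1.30 for SUSD2. The value of APOBEC3A is uncertain, because near-identical APOBEC3 genes can share its reads.

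**Figure D1:**
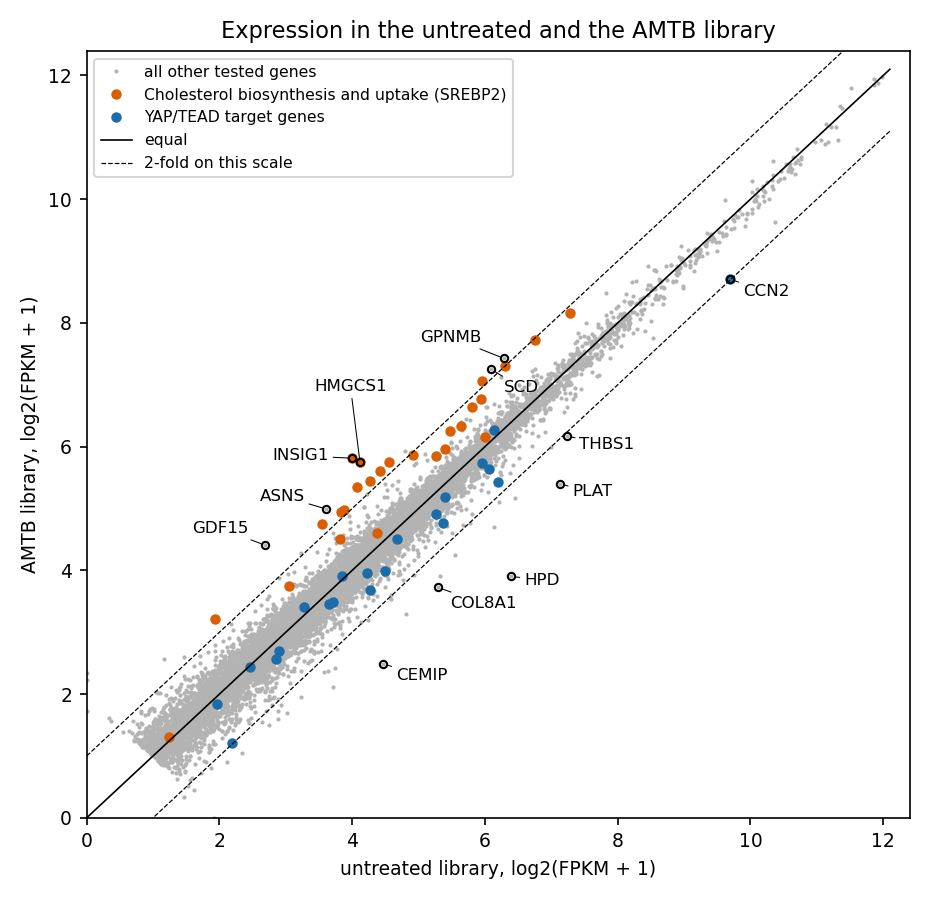
Expression of 11497 genes as log2(FPKM + 1) in the untreated library (x axis) and in the AMTB library (y axis), with 1 library per axis; the solid line marks equal values and the dashed lines 2-fold. Cholesterol genes (orange) sit above the solid line, with INSIG1 at 14.9 and 55.3 FPKM, and 18 of 21 YAP/TEAD target genes (blue) sit below it, with CCN2 at 828 and 417 FPKM.

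For the channel and the pathway in question, TRPM8 itself was barely recorded, and components and targets of TGFβ signalling gave a mixed picture. TRPM8 (Entrez Gene 79054; chromosome 2, 233917373 to 234019522) measured 0.33 FPKM untreated and 0.61 FPKM with AMTB, equal to about 18 and 34 reads, a ratio of 1.85 (1.02 to 3.5). Of 27 measured genes in the list named for TGFβ ligands, receptors and SMADs, 16 lay below 0 and 11 above. Their median was -0.13 on the log2 scale, at percentile 0.19 among 10000 random lists of like expression. The list also holds other genes, such as LTBP1, SMURF1 and ITGAV, and inhibitors of the pathway, such as SMAD6 and BAMBI. Its median therefore gives no direction of signalling. None of the 27 genes was at least 2-fold lower and 3 were at least 1.5-fold lower. These were TGFB2 (Entrez Gene 7042; chromosome 1, 218345336 to 218444619), INHBA, a subunit of activin, and BAMBI, a decoy receptor. TGFB2 measured 3.55 and 1.31 FPKM, -0.98 on the log2 scale and 2.71-fold lower as a plain ratio. With a pseudocount of 0.1, TGFB2 was at -1.37 and INHBA at -1.06.

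The most abundant ligand, TGFB1, measured 75.2 FPKM untreated and 64.8 FPKM with AMTB (-0.21), and TGFB3 2.28 and 2.32 FPKM (0.02). For the receptors, TGFBR1 measured 13.5 and 11.4 FPKM (-0.23) and TGFBR2 15.1 and 11.8 FPKM (-0.33). The signal-transducing SMADs differed little, at 0.15 for SMAD2, -0.14 for SMAD3 and 0.02 for SMAD4. Counting intervals of the ratio included 1 for SMAD3 (0.82 to 1.004) and SMAD4 (0.91 to 1.14), so that counting error could account for these differences. The SMAD3 interval only just did so, and its width depends on the transcript length used. Intervals excluded 1 for SMAD2 (1.03 to 1.23), TGFB1 (0.81 to 0.92), TGFBR1 (0.76 to 0.94) and TGFBR2 (0.70 to 0.88). Their widths depend on the transcript lengths used as well. The SMAD2 interval lay close to 1, so SMAD2 and SMAD3 cannot be set apart by these intervals. None of the intervals covers variation between cultures.

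The TGFβ/SMAD target list did not stand apart as a whole: its 32 measured genes had a median of -0.03, at percentile 17.83, and of 0.02, at percentile 61.88, among those with a mean FPKM of at least 5. Its members went both ways. CCN2 (Entrez Gene 1490; chromosome 6, 131948176 to 131951372), a matricellular protein also known as CTGF, measured 828 and 417 FPKM, 1.99-fold lower (ratio 0.50, 0.49 to 0.52). THBS1 (Entrez Gene 7057; chromosome 15, 39581079 to 39599466), or thrombospondin, measured 149 and 71.1 FPKM, 2.10-fold lower, and the collagen gene COL3A1 53.9 and 26.1 FPKM, 2.06-fold lower. BHLHE40 measured 29.4 and 51.0 FPKM, 1.73-fold higher, and ANGPTL4 53.9 and 85.6 FPKM, 1.59-fold higher. The inhibitory SMAD7 measured 14.3 and 14.8 FPKM, a ratio of 1.03 (0.84 to 1.28). CCN2 lay on the edge of 2-fold, at -0.99 as deposited and at -1.01 with log2 differences centred on the median of all genes.

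YAP/TEAD and BMP/ID target genes were lower as groups, while epithelial-mesenchymal transition and matrix genes were not called. YAP/TEAD target genes had a median of -0.23, lower than in all 10000 random lists, and 18 of 21 lay below 0. Besides CCN2 and TGFB2, CCN1 measured 72.3 and 41.9 FPKM and CRIM1 40.4 and 26.2 FPKM. BMP/ID target genes had a median of -0.40 over 14 genes, again lower than in all 10000 random lists, with 12 genes below 0. GREM1 and NOG, both secreted BMP antagonists, measured 69.3 and 25.1 FPKM and 5.69 and 1.82 FPKM, 2.76-fold and 3.13-fold lower, while MSX2 was at 0.62. These antagonists and the ligands BMP2 (-0.71) and BMP4 (-0.64) held the lowest values of the BMP/ID list. ID3 was at -0.55, ID1 at -0.43, ID2 at -0.14 and ID4 at -0.10. Because the list pools antagonists and ligands with ID genes, its median gives no direction of BMP signalling. Epithelial-mesenchymal transition genes had a median of -0.10 over 22 genes, at percentile 3.26, with CLDN1 at -0.86 (-1.11 with a pseudocount of 0.1) and KRT18 at -0.70. Both of these are epithelial genes. The list pools such genes with mesenchymal ones, such as VIM at 0.29 and SNAI2 at -0.47, so its median gives no direction of the transition. That list passed below the 2nd percentile with a pseudocount of 0.1 (1.87), without the filter on low values (1.44) and in random lists also matched on transcript length (1.64). With length and GC trends removed it was at percentile 0.01. Extracellular matrix and protease genes stood at the middle of random lists (median -0.005 over 36 genes, percentile 56.98), with 1 gene at least 2-fold higher and 3 at least 2-fold lower. The higher one was VCAN, the proteoglycan versican, at 8.36 and 18.4 FPKM, and the lower ones were COL8A1, THBS1 and COL3A1. VCAN was at 1.05, and at 0.93 with length and GC trends removed.

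The highest median of any list was in sterol synthesis. All 26 measured genes of cholesterol synthesis and uptake, a list named for the transcription factor SREBP2, were higher in the AMTB library, 22 of them at least 1.5-fold and 11 at least 2-fold. Their median was 0.96 on the log2 scale, with a counting interval of 0.89 to 1.01 and above all 10000 random lists. The smallest differences were those of TM7SF2 at 0.06 and of SREBF2, the gene of SREBP2 itself, at 0.16. DHCR7, which completes cholesterol synthesis, measured 15.9 and 39.9 FPKM, CYP51A1 22.4 and 53.2 FPKM and IDI1 20.5 and 47.7 FPKM.

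Fatty acid synthesis genes also stood higher, with a median of 0.44 over 15 genes, above all 10000 random lists, and 13 genes above 0. SCD, which desaturates stearate, measured 67.5 and 151 FPKM, 2.24-fold higher, and ACSS2 14.5 and 28.3 FPKM. LXR target genes, which respond to oxysterols, had a median of -0.19 over only 5 genes, at percentile 4.61. Without the filter on low values that percentile was 1.11. The 5 genes include NR1H3 and NR1H2, which encode the LXR receptors, and lack the list members ABCA1 and ABCG1. Lysosome and autophagy genes had a median of 0.18 over 41 genes, above all 10000 random lists, with 8 genes at least 1.5-fold higher and 1 at least 1.5-fold lower. GPNMB, a lysosome-associated glycoprotein, measured 76.8 and 171 FPKM, 2.23-fold higher, and NPC1, the lysosomal cholesterol transporter, 17.7 and 36.7 FPKM, 2.08-fold higher. NPC1 lay just under 2-fold once the log2 differences were centred on the median of all genes (0.99).

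**Figure D2:**
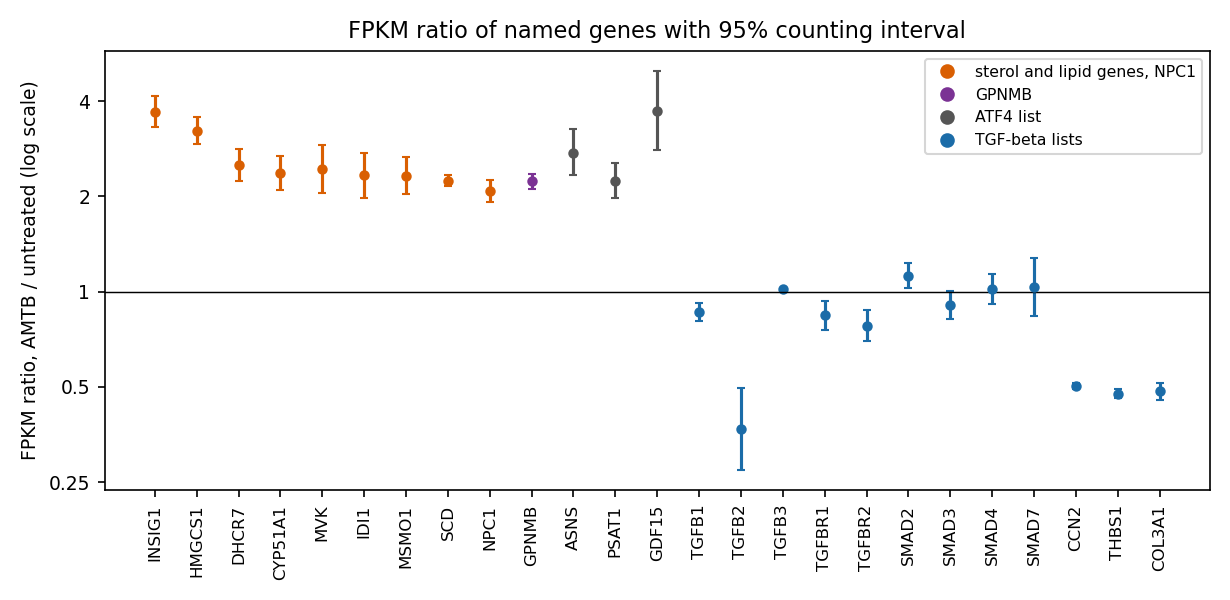
FPKM ratio of the AMTB library to the untreated library (log y axis, 1 library each) for 25 named genes, with bars for the 95% interval of counting error only (none for TGFB3, which had no transcript length here). Sterol and lipid genes, GPNMB and ATF4-list genes lie above 2, TGFB1, TGFB3 and the SMADs lie near 1, CCN2, THBS1 and COL3A1 lie near 0.50, and TGFB2 lies at 0.37.

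Genes of the amino acid and integrated stress response, a list named for the transcription factor ATF4, were higher as a group. Their median was 0.39 over 36 genes, above all 10000 random lists, 35 genes lay above 0, and 4 were at least 2-fold higher. Beside GDF15 these were the biosynthetic enzymes for asparagine and serine: ASNS at 11.2 and 30.8 FPKM, PSAT1 at 26.8 and 60.1 FPKM and PHGDH at 78.5 and 159 FPKM. PHGDH lay at 0.98 with centring on the median of all genes. Endoplasmic reticulum chaperone genes of the unfolded protein response were higher by smaller amounts, with a median of 0.30 over 23 genes, above all 10000 random lists. All 23 lay above 0 and none reached 1.5-fold. HSPA5, the chaperone BiP, measured 310.5 and 407 FPKM, and DNAJC3 18.03 and 25.68 FPKM.

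Cell death and p53 genes did not stand apart. The p53 target list had a median of 0.05 over 27 genes, at percentile 62.41, although CDKN1A, the cell cycle inhibitor p21, measured 14.6 and 26.4 FPKM, 1.80-fold higher. SESN1 measured 3.53 and 1.92 FPKM. BCL2 family and cell death genes had a median of 0.13 over 25 genes, at percentile 97.92. That list crossed the 98th percentile under 7 of the alternatives, at percentiles from 98.02 to 98.39. BCL2L11, the death-promoting protein BIM, measured 1.40 and 3.34 FPKM (0.85, and 1.20 with a pseudocount of 0.1), and BCL2L1, the survival protein BCL-XL, 43.3 and 32.1 FPKM.

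Proliferation lists were slightly higher in the AMTB library, with no gene at 1.5-fold in either direction. G1/S and DNA replication genes had a median of 0.10 over 41 genes, at percentile 99.68, with CDC6 at 28.7 and 38.5 FPKM and UNG lower at 35.6 and 24.7 FPKM. G2/M and mitosis genes had a median of 0.09 over 40 genes, at percentile 98.79, with MKI67 at 66.8 and 85.4 FPKM. Neither call held against random lists not matched on expression, at percentiles 97.88 and 94.65. For G2/M it was also lost at a mean FPKM of at least 5 (97.68) and with length and GC trends removed (64.87). Replication-dependent histone genes had a median of -0.28 over 7 genes, at percentile 0.36, and at 2.66 with those trends removed. Messages of this class mostly lack poly(A) tails, which was not examined for these 7 genes. Some of the genes were low here, with H4C3 at about 1 and 8 reads. DNA repair genes (median 0.06 over 30 genes, percentile 82.89) and growth control factors (median 0.04 over 11 genes, percentile 64.27) did not stand apart. Among the latter, MYC measured 129 and 108 FPKM.

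**Figure D3:**
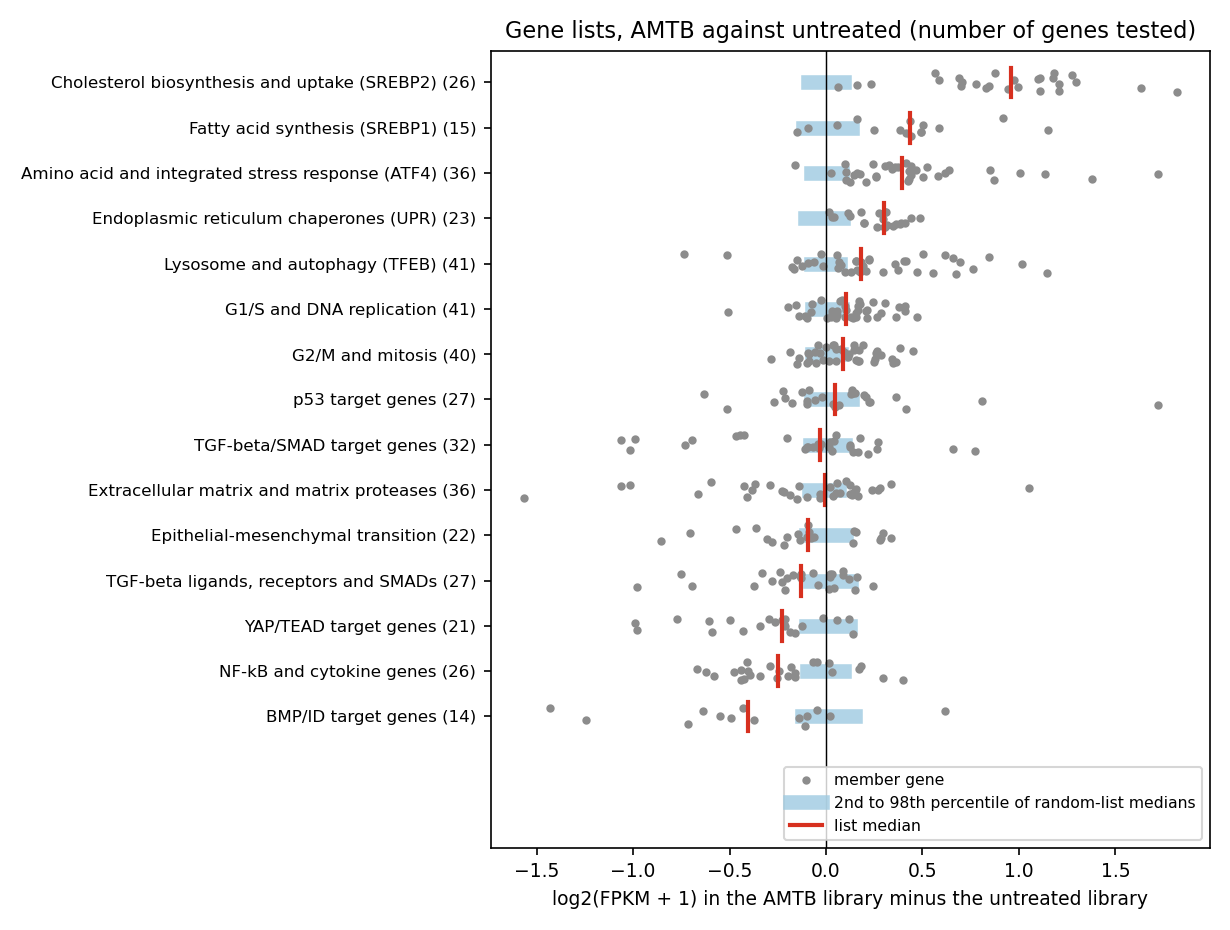
Difference in log2(FPKM + 1) between the AMTB and the untreated library (x axis) for the members of 15 gene lists (grey points, number of genes in brackets), with the list median (red) and the span from the 2nd to the 98th percentile of 10000 random-list medians (blue). The cholesterol list has a median of 0.96 and the ATF4 list 0.39, the TGFβ/SMAD targets lie inside the random span at -0.03, and YAP/TEAD and BMP/ID targets lie below it at -0.23 and -0.40.

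Calcium, lineage and growth factor lists did not stand apart as groups. TRP channel and calcium genes had a median of -0.08 over 21 genes, at percentile 3.76, with RCAN1 the lowest and the channel TRPA1 at 13.4 and 6.86 FPKM. That list passed below the 2nd percentile in random lists also matched on transcript length (1.37) and with length and GC trends removed (1.56). Osteoblast lineage genes had a median of 0.05 over 11 genes, at percentile 79.34, and -0.27 at percentile 0.03 among those with a mean FPKM of at least 5. TNFRSF11B, or osteoprotegerin, measured 1324 and 792 FPKM, 1.67-fold lower. Immediate-early genes (median -0.05 over 23 genes, percentile 12.9), ERK targets (-0.07 over 19 genes, percentile 8.79) and WNT targets (-0.12 over 12 genes, percentile 3.41) showed no call. Among WNT targets, APCDD1 measured 3.35 and 0.86 FPKM. Cytoskeleton and SRF/MRTF target genes had a median of -0.09 over 24 genes, at percentile 5.17, with ACTB at 2544 and 1986 FPKM. Hypoxia and glycolysis genes had a median of 0.05 over 34 genes, at percentile 92.12, and 99.85 with length and GC trends removed. Their largest difference was ENO2, a glycolytic enolase, at 6.42 and 13.7 FPKM (0.99, and 1.08 with a pseudocount of 0.1).

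Markers of other cell types had fewer than 5 measured members per list and so no percentile. Blood cell markers reached 26.7 and 30.4 FPKM for CD68 and otherwise at most 5.90 FPKM, for LYZ. Endothelial markers reached 7.74 and 6.97 FPKM for ERG. The epithelial keratin KRT7 measured 54.6 and 34.2 FPKM, while EPCAM was at 0.12 FPKM in the untreated library and listed at 0 with AMTB. Liver and kidney markers reached 1.71 and 1.41 FPKM for PAX8.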

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

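Tests with length and GC trends removed, with random lists matched on length, and with shared members left out were chosen after the results were seen. The cholesterol list and the list of TGFβ ligands, receptors and SMADs kept their direction and call under every alternative run, with cholesterol medians from 0.93 (trimmed mean scaling) to 0.99 (sum of 1000000). The counts of genes depended on the settings. The 26 higher and 34 lower genes became 65 and 77 with a pseudocount of 0.1, 173 and 210 at 1.5-fold, and 6 and 4 at 3-fold. Rescaling to a sum of 1000000 gave 46 higher genes. That step raised all FPKM, so that the pseudocount of 1 weighed less, and moved the median difference of all genes from 0.02 to 0.05. The shares of these effects were not separated. A mean FPKM of at least 5 left 21 lower genes among fewer genes tested. No list or gene with a call changed sign. Among those without one, 4 lists and 4 named genes did. The TGFβ/SMAD target list, never called, went from -0.03 to 0.02 at a mean FPKM of at least 5, and the osteoblast list from 0.05 to -0.27, where it gained a call. Of 34 lists, 22 kept their call throughout and 12 did not. In 16 comparisons a list gained a call and in 13 it lost one, where the cause was not tested. The ribosomal protein list lost its call most often, in 5 comparisons, 4 of them between percentiles 2.06 and 2.37. Of 160 named genes, 147 stayed on their side of 2-fold. Depth limits low genes most: between 1 and 5 FPKM the spread of log2 differences was 0.30, against 0.20 from simulated counting error, and above 100 FPKM 0.21 against 0.04. Beyond counting error, the spread between cultures was not measured, and no alternative stands in for it.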

Other observations

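In this part, every test with length and GC trends removed or with random lists matched on length, the tests on LXR targets and on the other TGFβ/SMAD targets, and the YAP/TEAD list without shared members were chosen only after results were seen. The scalings were fixed in advance, but their use as a test of the cholesterol list was chosen afterwards. Inflammatory and interferon genes differed in opposite directions. NF-kB and cytokine genes had a median of -0.25 over 26 genes, lower than in all 10000 random lists, with 20 genes below 0. NFKBIA, the NF-kB inhibitor, measured 48.1 FPKM untreated and 31.8 FPKM with AMTB, and the chemokine CXCL1 362 and 260 FPKM. Interferon-stimulated genes had a median of 0.17 over 31 genes, at percentile 99.99, with 24 genes above 0. The RNA sensor IFIH1 measured 8.36 and 12.5 FPKM, while OASL was lower at 56.3 and 39.7 FPKM.

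Heat shock genes had a median of 0.13 over 17 genes, at percentile 99.86, with HSPH1 at 34 and 54.2 FPKM and HSP90AA1 at 297 and 403 FPKM. The call was lost in unmatched random lists (96.68). Metallothionein and zinc response genes had a median of 0.20 over 9 genes, at percentile 99.01, with 5 genes above 0 and 4 below. That call was lost at a mean FPKM of at least 5 (77.01) and with length and GC trends removed (86.2). NRF2 target genes had a median of -0.09 over 25 genes, at percentile 3.92. Their lowest members were AKR1C1 at 44.2 and 23.3 FPKM, AKR1C2 at 8.35 and 4.16 FPKM and AKR1C3 at 16.5 and 7.95 FPKM. Reads can be split between these near-identical paralogs, so their values are uncertain, while HMOX1, or heme oxygenase, measured 6.01 and 10 FPKM. Ribosome biogenesis and MYC target genes had a median of -0.07 over 28 genes, at percentile 8.26, with NOB1 at 35.1 and 23.7 FPKM.

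The cholesterol list was higher in the AMTB library, by a median of 0.96 on the log2 scale. Counting error alone reached at most 0.0416 in 1000 simulated pairs, the lowest median over 4 other scalings was 0.9333, and the median with length and GC trends removed was 0.9896, all of which argue against these sources. A low-sterol signal in the treated cells is a candidate explanation, and such a signal could also leave LXR targets lower. Those had a percentile of 4.61 over 5 genes and of 1.11 with no filter on mean FPKM, on either side of the 2nd percentile that the test asked for, so this explanation stays open. The 5 genes include the LXR receptor genes NR1H3 and NR1H2, so their median is a limited measure of LXR output. With 1 library per group, AMTB cannot be told apart from any other difference between the cultures, such as density, medium or solvent.

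CCN2, THBS1 and COL3A1 were about 2-fold lower, in a TGFβ/SMAD list that did not stand apart. A uniform loss of SMAD-dependent transcription would lower the other 29 genes by about as much. Their median was 0.0182 (SD over genes 0.33). CCN2, THBS1 and COL3A1 were the lowest members of the list, so leaving them out raises the median of the rest. With them included, the median of all 32 genes was -0.03. Both medians argue against a uniform loss. An uneven one stays open, with BAMBI at -0.69 and NEDD9 at -0.73. Lower YAP/TEAD output may contribute: without members of the TGFβ lists, 19 YAP/TEAD genes had a median of -0.2155, lower than in all 10000 random lists. This is a hypothesis only, since THBS1 and COL3A1 are not in the YAP/TEAD list, and the TGFβ/SMAD list without CCN2 was at -0.03. A difference between the cultures other than AMTB stays open here too.

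Ribosomal protein genes were slightly lower, with a median of -0.10 over 64 genes (percentile 1.84), and so were nuclear-encoded oxidative phosphorylation genes, with -0.12 over 38 genes (percentile 0.45). The ribosomal call was weak: it was also lost with pseudocounts of 0.1 (2.1) and 0.5 (2.06), rescaling to a sum of 1000000 (2.1) and random lists also matched on length (2.37), at medians from -0.10 to -0.07. Across genes, which are not independent replicates, the log2 difference correlated with log2 transcript length (r = 0.13) and GC content (r = -0.22). With both trends removed, the ribosomal median was -0.02 at percentile 16.58, so that length or GC bias of the libraries could account for it. The oxidative phosphorylation median was -0.10 at percentile 0.01 after the same step, which argues against that bias as its whole source, with SDHA at 209 and 142 FPKM. A difference between the cultures, with or without AMTB, stays open for both lists.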
